A study of Drosophila melanogaster with 3 samples.

How the data were processed

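Single cells of 3 Drosophila melanogaster cell lines derived from the intestine, L10, L15 and L18, were profiled with 1 droplet library of 3' ends (10x Genomics, version 3.1 chemistry) per line, per the labels. The deposited matrix of L10 holds raw counts of unique molecular identifiers (UMIs), whole numbers that had not been scaled, for 13987 features in 16189 barcodes. The submitters' processing notes name Cell Ranger 7.0.1 and 7.2, Seurat 4 and the genome build BDGP6, without saying which step each served, and whether reads from introns were counted is not given in the sources used here. For L15 and L18 the lists of barcodes and features were used, and their expression is not analysed here. The 3 feature lists were identical. Of the 13986 features other than the row for green fluorescent protein (GFP), 13976 had an identifier in the BDGP6.54 annotation, all of them protein-coding genes, and 10 had none. Coordinates are those of that annotation.

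Each line had 1 library, and the lines were at 3 different passages, so no test between lines was made and no p-value is given. Cells are not replicates. Sums of UMIs carry exact Poisson 95% intervals, shares of cells exact binomial (Clopper-Pearson) 95% intervals, and folds of summed UMIs the exact conditional interval. All of these cover counting error only. For a count of 0, the limit that 3 UMIs would give is used. L10 barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept. Levels are UMIs summed over the kept cells per 1000000 UMIs (CPM). For shares of cells and for comparisons between cells, each cell was thinned at random to 7000 UMIs, the 25th percentile rounded down to a multiple of 500, which left 11271 cells and set aside 3501 shallower ones.

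Kept cells were scaled to 10000 UMIs and log transformed, and 2000 variable genes, 30 principal components and 15 exact nearest neighbours were used for Leiden clustering at resolution 0.5 (scanpy 1.11.5, leidenalg 0.10.2, umap-learn 0.5.12, scikit-learn 1.9.0, Python 3.11.15). The leading genes of a cluster were the 10 with the highest fold over all other kept cells among genes of at least 50 CPM in it. A cluster took the name of a cell type list where at least 3 markers reached 10 CPM at 2 times the level of the other cells or more, at least 1 of them was among its 10 leading genes, and both held when the cell with most UMIs of each marker was left out. The markers were fixed before the data were examined, and this scoring rule, with the removal of the highest cell, was set after the clusters were seen. Clusters under 50 cells were not described. Scrublet marked 0 of the 14772 kept cells as doublets. Its threshold of 0.593 was passed by only 0.0372% of its own simulated doublets (median score 0.129), so its calls were not used and doublets were kept.

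For the cell cycle and MAPK target splits, the thinned cells in the top 25% by the summed UMIs of a gene list were compared with those in the bottom 25%, leaving that list out and keeping genes with at least 500 UMIs in both classes together. These classes are ranges of a continuous score, not cell types. The median log2 fold of each other list with at least 3 compared members was placed among 10000 random lists of equal size matched on expression in 20 bins. Such a percentile describes this library only. Pairs of markers were compared where both genes had a UMI in at least 1% of thinned cells, and the variance over the mean (Fano factor) was taken for genes with a mean of at least 0.05 thinned UMIs. A planned split by roX1 and roX2 and 2 planned pairs with roX1 were not run, as neither gene is among the features used here. Of the fixed lists, dys, phl, Gap1 and Eip71CD found no feature by their symbols, and hnt, dad, DNApol-alpha50 and DNApol-alpha180 were read as peb, Dad, Prim1 and PolA1.

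The genes named were fixed before the data were examined: of each list up to 4 members of highest CPM plus the defining markers, the 20 most abundant nuclear genes that encode no cytoplasmic ribosomal protein, the 15 largest folds in each direction per split, the 30 highest Fano factors, the leading genes of clusters as their description, CG10116 and Ras85D. GFP, w, y, Hsp70Bb, msl-2, the trypsin genes at 0 UMIs and markers named for single clusters lie outside this rule and were chosen after their values were seen. For the named genes of each split and of the Fano factor, values were also taken without the cell of highest count, and the named genes of each split with classes formed within clusters, checks added after the data were seen. Alternatives covered cell filters, random subsets of cells, CPM denominators and minimums, clustering settings, class sizes, thinning depth and UMI minimums. For the label of a list median, the interval came from 200 Poisson redraws of its members' UMIs.

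The functions were tested on simulated cells of 7000 UMIs drawn from the real gene means. In the simulated cell cycle split all 67 genes changed 1.5-fold, all 67 changed 2-fold and all 66 changed 4-fold had an interval apart from 1, and so did 177 of 3613 unchanged genes, or 4.90%. In the simulated MAPK target split the same held for 67 of 67, 67 of 67 and 62 of 62 changed genes and for 165 of 3597 unchanged genes. Of 100 lists of 12 unchanged genes, 1 in the cell cycle split and 2 in the MAPK target split fell outside the central 95% of random lists. Clustering returned the 4 simulated kinds of cells as 4 clusters. The median Fano factor over 6224 genes of 1 simulated kind was 0.999. The simulated intervals were first divided by the median fold of the unchanged genes, a step that the real folds did not get. Simulated cells of 1 kind vary by counting error only, so these rates do not hold for real genes that vary more between cells.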

Results

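The L10, L15 and L18 lines came from the Drosophila intestine and carry a CG10116-GAL4 driver with UAS-6XGFP and UAS-Ras[V12], a constitutively active form of the Ras GTPase. They were grown as adherent cultures, and each gave 1 library, so no value between lines has a replicate check. L10 was at passage 4, L15 at passage 18 and L18 at passage 16. The barcode lists held 16189 cells for L10, 17139 for L15 and 19564 for L18. The L10 matrix summed to 205303862 UMIs, with a lowest total of 500 and a highest of 284087 UMIs per barcode. After filtering, 14772 L10 cells (91.2%) remained, with a median of 11480 UMIs and 2345 genes per cell and a median mitochondrial share of 2.61%. Of the barcodes left out, 1339 had too few genes and 78 only too high a mitochondrial share. Ribosomal protein genes took 27.9% of the UMIs of kept cells.

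The lists were compared for shared barcodes as a check for carry-over between libraries. L10 and L15 shared 79 barcodes, L10 and L18 shared 86, and L15 and L18 shared 87. The L10 barcodes also found in L15 had a median of 10249 UMIs against 10616 for the other L10 barcodes. Those also found in L18 had a median of 10951 UMIs against 10611.

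Which lineages the L10 cells resembled was asked first through fixed marker lists. Markers of enterocytes and copper cells were nearly absent. Of 16 enterocyte markers only 1, Myo31DF, an unconventional myosin, reached 10 CPM, at 57.5 CPM (95% interval 56.4 to 58.5). The enterocyte transcription factor nub stood at 0.353 CPM (0.276 to 0.445), and the amylase gene Amy-p, the highest of the digestive enzyme genes, at 0.118 CPM. The markers lambdaTry, betaTry and deltaTry had 0 UMIs in 14772 cells, which allows at most 0.0147 CPM for each. That limit holds only for UMIs assigned to the gene. Of 5 copper cell markers none reached 10 CPM, the highest being Vha100-4 at 1.21 CPM. Of 19 enteroendocrine markers 3 reached 10 CPM, the neurohormone genes ITP (86.7 CPM) and Nplp2 (67.1 CPM) and the peptide-processing enzyme gene Phm (54.4 CPM). The enteroendocrine regulator pros stood at 9.86 CPM (9.44 to 10.3), and Tk at 2.52 CPM.

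Of 12 progenitor markers 8 reached 10 CPM, led by hdc at 1861 CPM, N, the Notch receptor, at 432 CPM, E(spl)mbeta-HLH at 264 CPM and Pdk1 at 151 CPM. Dl, the Notch ligand of intestinal stem cells, stood at 51.5 CPM (50.5 to 52.5) with a UMI in 22.8% of cells and in 18.3% after thinning. The Snail family factor esg, the usual marker of stem cells and enteroblasts, was at 0.868 CPM (0.745 to 1.01), with a UMI in 0.941% of cells and in 0.497% after thinning. By cluster, both were highest in cluster 13, with esg at 7.76 CPM and Dl at 223 CPM. The labels name no L10 cell type that should lack these genes, and the trypsin gene epsilonTry, for comparison, had a UMI in 0.0406% of kept cells and in 0.0177% of thinned cells. CG10116, whose regulatory sequence drives GAL4 in these lines (3L, 13456208 to 13457238, minus strand), was at 1.06 CPM (0.927 to 1.22) with a UMI in 1.21% of cells (1.04 to 1.40) and in 0.754% after thinning. GFP stood at 1531 CPM (1526 to 1537), with a UMI in 83.3% of cells and in 83.2% after thinning, and Ras85D (3R, 9510561 to 9513067, minus strand) at 271 CPM (269 to 274), a value that does not separate the endogenous gene from the UAS-Ras[V12] transgene.

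Markers of lineages outside the gut epithelium were mixed. Of 14 hemocyte markers 11 reached 10 CPM. The highest were Fer1HCH, a ferritin subunit that many cell types also express, at 1604 CPM, the engulfment receptor gene NimC4 at 334 CPM, Ppn at 218 CPM and the GATA factor gene srp at 135 CPM, while Hml stood at 58.9 CPM. Of 13 muscle markers 6 did, with sls at 71.2 CPM, Mef2 at 63.7 CPM, Mlc1 at 16.7 CPM, Act57B at 14.9 CPM and Mhc, the muscle myosin heavy chain gene, at 6.72 CPM. Of 10 neuron markers 5 did, including elav at 111 CPM, brp at 71.1 CPM, fne at 21.7 CPM and para at 21.0 CPM. The other cell type lists had few members at that level. They were 2 of 7 tracheal markers (vvl at 39.6 CPM and verm at 14.4 CPM, with trh at 0.681 CPM), 2 of 7 glial markers (nrv2 at 71.1 CPM and moody at 40.2 CPM, with repo at 1.63 CPM), 1 of 9 fat body markers (apolpp at 35.9 CPM) and 1 of 7 Malpighian tubule markers (tup at 38.3 CPM). Of 6 hindgut markers dve alone did so at 18.5 CPM, and of 8 germline markers AGO3 (108 CPM) and aub (11.4 CPM) did, with vas at 0.172 CPM. Of 10 imaginal disc or epidermis markers 5 did, led by sd at 198 CPM, ci at 150 CPM and ptc at 84.3 CPM. In all, 48 of 141 distinct cell type markers reached 10 CPM. The share of all features at that level is not given here, so such counts, above and below, have no background to be read against.

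Targets of Ras and MAPK signalling were abundant. Of 12 MAPK targets 11 reached 10 CPM, led by kek1 (1163 CPM), aop (779 CPM), sty (732 CPM) and pnt (687 CPM), and of 13 Ras pathway components 11 did, with cic at 203 CPM and Egfr, the EGF receptor gene, at 15.6 CPM. All 9 Hippo list members did, with Myc at 1342 CPM, Diap1 at 532 CPM and kibra at 230 CPM. All 14 basement membrane and matrix genes did, with SPARC at 563 CPM, trol at 464 CPM, Mmp1 at 279 CPM and Col4a1 at 243 CPM, as did all 13 glycolysis genes, with Ldh at 2048 CPM, Eno at 1464 CPM and Ald1 at 1263 CPM. Of 20 junction and polarity genes 17 did, with pyd at 259 CPM and scrib at 230.5 CPM, while the smooth septate junction genes Tsp2A, Ssk and mesh, typical of the gut epithelium, stood at 2.44, 1.95 and 0.348 CPM. Notch targets reached 10 CPM in 12 of 14 cases, including E(spl)m3-HLH (241 CPM), E(spl)malpha-BFM (195 CPM) and E(spl)m2-BFM (181 CPM).

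At 10 CPM or more were 8 of 15 gut transcription factors (ttk at 178 CPM, da at 118 CPM, but GATAe only at 0.740 CPM), 8 of 9 JAK-STAT genes (Socs36E at 449 CPM, chinmo at 214 CPM) and 9 of 11 JNK and stress genes (puc at 337 CPM, kay at 307 CPM). The BMP, Wnt and Hh list had 9 of 12 (nkd at 136 CPM, Mad at 87.0 CPM), the ecdysone list 8 of 13 (ImpL2 at 748 CPM, ftz-f1 at 658 CPM, br at 575 CPM) and the immune effector list 9 of 19 (Drs at 1422 CPM, AttD at 99.2 CPM, Rel at 94.3 CPM, Mtk at 82.7 CPM). The S phase list had 14 of 17 (PCNA at 206 CPM, RnrL at 112 CPM) and the G2/M list 23 of 24 (stg at 274 CPM, feo at 198 CPM). The heat shock list had 12 of 15 (Hsc70-4 at 2464 CPM, Hsp23 at 1838 CPM), the iron and metal list 4 of 8 (Fer2LCH at 1983 CPM, MtnA at 107 CPM) and the sex and dosage compensation list 8 of 10 (Sxl at 222 CPM, fru at 128 CPM, msl-2 at 12.1 CPM). Among 11 Hox and region genes only Antp (49.8 CPM) and hkb (14.7 CPM) did, and Abd-B, Ubx and lab stayed at or under 1.24 CPM.

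The most abundant nuclear transcript outside the ribosomal protein genes was assigned to DIP-alpha, which encodes a cell adhesion protein of the immunoglobulin family known from neurons (X, 3507245 to 3571649, minus strand). It took 13.6% of the UMIs of kept cells and was found in all 14772 of them, with a median of 13.3% of a cell's UMIs and 5th and 95th percentiles of 4.81% and 26.6%. Its span holds the noncoding RNA gene CR34335 in an intron on the same strand (X, 3545750 to 3546110), and all 13976 features found in the annotation were protein-coding genes. Next came Arc1 (8532 CPM), pAbp (7351 CPM), eEF1alpha1 (7164 CPM) and blot (6562 CPM, 3L, 17396031 to 17421514, minus strand), whose intron holds the noncoding RNA gene noe (3L, 17400272 to 17401348). The remaining 15 of the 20 most abundant, from aqz (3077 CPM) to eEF2 (1665 CPM), were aqz, fax, Hsc70-4, eIF4A, eEF5, cib, Act5C, Tctp, Ldh, Jafrac1, Fer2LCH, tsr, hdc, Hsp23 and eEF2.

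**Figure D1:**
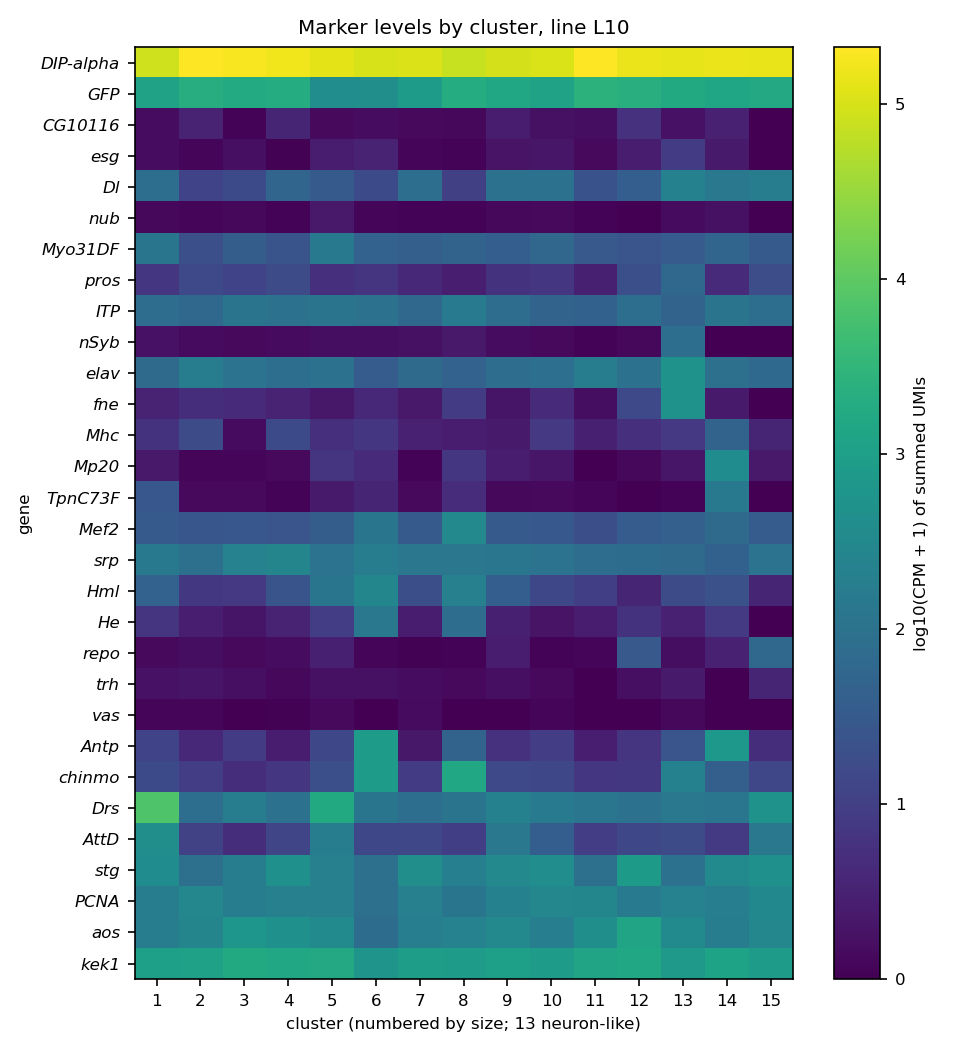
Levels of 30 genes (rows) in the 15 L10 clusters of at least 50 cells (columns), as log10 of CPM + 1 of UMIs summed over each cluster's cells. DIP-alpha was high throughout, CG10116 stood at or under 4.77 CPM, esg at or under 2.33 CPM outside cluster 13 (7.76 CPM), fne (529 CPM) and nSyb (84.1 CPM) stood out in cluster 13, Drs (7247 CPM) in cluster 1, Antp in clusters 6 and 14 and chinmo in clusters 6 and 8, whereas the Mp20 level of cluster 14 came from 1 cell.

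The cells fell into 16 clusters, 15 of them with at least 50 cells, from 2589 cells (17.5%, 16.9 to 18.1) down to 57 cells (0.386%). Only cluster 13 could be named from the fixed markers. It was neuron-like, with 426 cells (2.88%, 2.62 to 3.17) and a median of 14320 UMIs. In it 7 of 10 neuron markers reached 10 CPM at 2 times the level of the other cells or more, and fne and nSyb were among its leading genes with nerfin-1, insb, Oli, scrt, VhaAC45RP, CG13920, phyl and 7B2. The RNA-binding protein gene fne stood at 529 CPM against 3.40 CPM in the other cells, and the synaptic vesicle gene nSyb at 84.1 against 0.615 CPM. After thinning, 73.1% of its cells (68.3 to 77.6) had a UMI of fne against 1.12% of the other cells. Of the 19 enteroendocrine markers, which include nSyb and Syt1 of the neuron list, 6 met the same criterion, among them pros at 61.8 CPM, Tk at 28.1 CPM and 7B2 at 68.3 CPM, with nSyb and 7B2 among the leading genes. The progenitor markers Dl, klu, mira and zfh2 met the criterion too, klu only with its highest cell included, as did the muscle markers Mlc1, bt and Prm, bt likewise, but none was a leading gene. The cluster thus met the naming rule for both the neuron and the enteroendocrine list, and the name taken is that of the list with the larger share of its markers met.

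Muscle genes in cluster 14 (139 cells, 0.941%, median 7666 UMIs) came in part from 1 cell. Of 13 muscle markers 9 met the criterion with all cells, and this cell held 1648 of their 2350 UMIs and the highest count of all 9, but only 60 of 142 UMIs of wupA, 133 of 313 of sls, 63 of 130 of bt and 12 of 44 of Prm. The highest marker, the muscle protein gene Mp20, stood at 388 CPM. The cell held 552 of its 553 UMIs, and without it Mp20 stood at 0.720 CPM against 1.71 CPM in the other clusters. The same step took Mlc2 from 304 to 61.2 CPM, Act57B from 322 to 124 CPM and Mhc below 2 times the level of the other cells, leaving 6 markers at the criterion (wupA at 59.1 CPM against 2.62 CPM in the other cells) but none among the leading genes, so the cluster stayed unnamed. Leading genes found in many of its cells were CG12075 (87 of 139 cells), CG4741 (71 cells) and unc-13-4A (68 cells). Cluster 15 (57 cells) had 4 of 7 glial markers at the criterion, among them the glial regulator repo at 58.2 CPM, and 2 without the highest cell of each. It also had 3 of 13 muscle markers at the criterion, and again 2 without the highest cell of each. The muscle marker up was found in 54 of its cells, at 383 CPM against 2.04 CPM in the other cells, and repo in 15. No marker of either list was a leading gene, and CG12607, CG6431 and CG14246 led this unnamed cluster. repo also stood at 29.3 CPM in cluster 12.

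The other clusters stayed unnamed and are described by leading genes. Cluster 1 (2589 cells) was led by CG13177, CG15657, the antimicrobial peptide genes Drs and Mtk, edin and Dro, with Drs at 7247 CPM against 288 CPM in the other cells. Cluster 2 (2424 cells) was led by blanks, inv and pippin, cluster 3 (1573 cells) by lft, ed, the JAK-STAT ligand genes upd2 and upd3, Egfr and Pxn, and cluster 4 (1217 cells) by CG4596, salm, salr and Wnt2. Cluster 5 (1052 cells) was led by CG14259, Ets65A, Tsf1 and org-1, cluster 6 (1040 cells) by CG15550, mthl12 and Toll-4, and cluster 7 (1020 cells) by CG8641, Tbh, ovo and brp. Cluster 8 (959 cells) was led by the odorant co-receptor gene Orco and by robo3, cluster 9 (700 cells) by CCHa2-R, unc-4 and Lim1, cluster 10 (632 cells) by MtnB and verm, cluster 11 (476 cells) by mirr and oc, and cluster 12 (447 cells) by Ca-alpha1T, orb and SoxN, while 1 cell held 1261 of the 1722 UMIs of its leading gene CG8369. Without the highest cell of each marker, 5 of 14 hemocyte markers met the criterion in cluster 8 (Hml at 210 CPM with all cells, He at 80.0 CPM, and NimC1, Sr-CI and Ppn) and 4 in cluster 1 (NimC4, eater, Sr-CI and Ppn), but none was a leading gene. In the same way 3 glial markers in cluster 1, 3 muscle markers in cluster 8 and 3 progenitor markers in cluster 12 (klu, mira and zfh2) met it. The requirement of a leading gene, set after the clusters were seen, thus kept cluster 1 (17.5% of cells), cluster 8 (6.49%) and cluster 12 (3.03%) without a name. Cluster 6 had a median of 6460.5 UMIs, the lowest of the 15.

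GFP differed between clusters, from 411 CPM (402 to 421) in cluster 5 to 2658 CPM (2623 to 2693) in cluster 11. After thinning, 46.0% of cluster 6 cells (41.4 to 50.7), 49.2% of cluster 5 cells (45.8 to 52.6) and 99.5% of cluster 11 cells (98.3 to 99.9) had a GFP UMI, with median depths before thinning of 6460.5, 14414 and 17034 UMIs. No cell type of L10 is known to lack GFP, so the share that free RNA gives was not measured. Within cluster 1, 21.6% of thinned cells had 0 GFP UMIs and 35.6% had 10 or more.

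**Figure D2:**
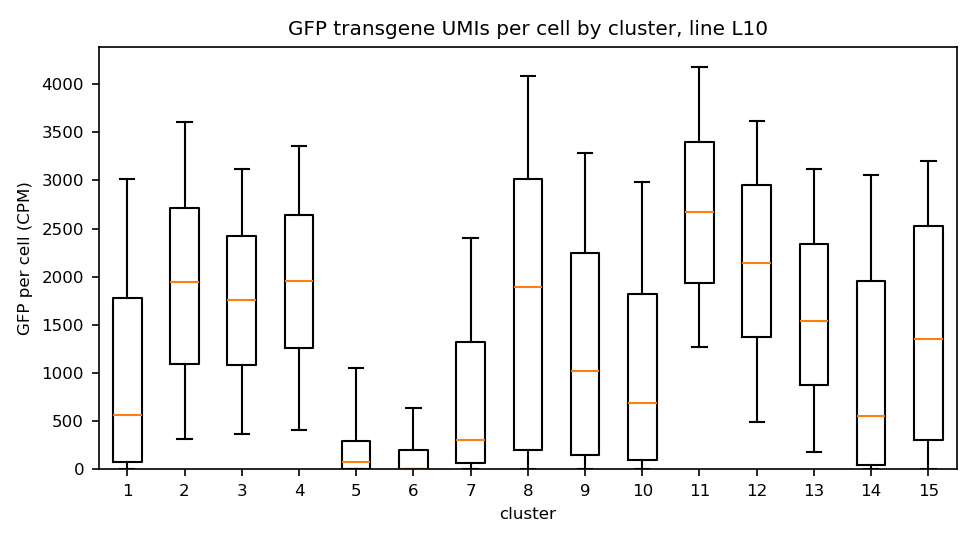
GFP per cell in CPM (vertical axis) for the 15 clusters of at least 50 cells (horizontal axis); lines within boxes are medians, boxes span the 25th to 75th and whiskers the 10th to 90th percentiles of cells. The median was 76.1 CPM in cluster 5, 0 in cluster 6 and 2674 CPM in cluster 11.

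To ask what varied with the cell cycle, cells in the top 25% by G2/M genes (10 UMIs of the list or more) were compared with cells in the bottom 25% (4 or fewer), 2817 cells each. The score is a plain sum of UMIs, so its most abundant genes weigh most. In the top class stg had 5.00 UMIs per cell against 0.363 in the bottom class, and feo 2.27 against 0.454. For CycB the values were 0.328 and 0.0401. The classes thus differ in large part by stg and feo. S phase genes were higher together in the top class. All 14 compared members had an interval above 1, and their median log2 fold of 1.46 lay above all 10000 random lists (central 95% 0.10 to 0.45). In random subsets of the cells, where 5 and 6 members could be compared, the median was 0.75 and 0.74. The largest folds were those of Ts, thymidylate synthase, at 5.89 (725 UMIs against 123), the checkpoint gene Claspin at 5.54 (4.38 to 7.07), and the replicative helicase genes Mcm7 at 5.49, Mcm6 at 5.13 and Mcm5 at 4.22. Mink (5.46), cmet (4.11), dup (3.99), CycE (3.69), msb1l (3.45), dpa (3.43), Ca-alpha1T (3.41), kuk (3.38), Spc105R (3.17) and nesd (3.07) followed. The median log2 fold of all 5233 genes compared was 0.23, the level against which list medians are read, and 79 genes were at least 2 times higher and 110 at least 2 times lower in the top class.

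Immune effectors were lower in the top class. All 8 compared members had an interval below 1, with a median log2 fold of -1.93 below all random lists, and Drs had 2.05 UMIs per cell against 13.9 in the bottom class, a fold of 0.148 (0.144 to 0.152). All 4 compared iron and metal genes were lower as well (median -1.20, percentile 0.01), including the transferrin gene Tsf1 at 0.126. The lowest folds were those of CG30148 (0.0641), CG13177 (0.0781), CG15550 (0.0983), CG14253 (0.125) and AttB (0.126), and Ance, Nplp2, kn, Idgf3, Antp, AttD, Mtkl and CG31676 lay between 0.143 and 0.199. The numbers of cells with a UMI differed less for some of these genes. For Drs they were 879 top and 1138 bottom cells, and for CG13177 43 and 55, with 195 of its 960 bottom UMIs in 1 cell. These 2 folds thus rest mostly on high counts in part of the cells. For CG30148 the numbers were 18 and 142 cells. Cluster makeup differed between the classes, since 57.5% of cluster 6 but 9.47% of cluster 12 fell in the bottom class, and with classes formed within clusters the folds of CG15550 and Antp turned above 1 and the immune effector median was -2.73. Of the 13 lowest genes that could be compared within clusters 7 moved by over 1.5 times, besides these 2 kn to 0.856, Ance to 0.843, Nplp2 to 0.566, Idgf3 to 0.417 and Tsf1 to 0.317, as did 1 of the 14 highest, Ca-alpha1T, to 1.63. The iron and metal median was -0.40 with unthinned counts. The heat shock (median -0.27), glycolysis (-0.28) and JNK (-0.25) medians lay below the central 95% of random lists, and those of the Notch targets (0.42) and MAPK targets (0.34) above it, though heat shock fell inside it without DIP-alpha counts (-0.048). The Hippo median (0.40) and imaginal disc median (0.49) lay just above it and fell inside it in 11 and 9 of 12 alternatives, the Hippo median also with classes formed within clusters (0.30, percentile 91.8). The muscle list median, -0.36 over 3 members, lay at percentile 1.92, fell inside it in 3 of 7 alternatives and turned to 0.11 without DIP-alpha counts. The remaining compared lists lay within the central 95%, but with classes formed within clusters the progenitor (0.35) and BMP, Wnt and Hh (0.38) medians lay above it and the hemocyte median (-0.047) below it. Within 1 UMI of the class limits lay 1677 and 3283 cells, and the median unthinned depth was 13978 UMIs in the top and 13034 in the bottom class. Without the cell of highest count in each class, none of these 30 folds changed sides, the largest shift being that of Mtkl from 0.188 to 0.126.

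The spread of Ras and MAPK output was examined in the same way, given the UAS-Ras[V12] transgene. Cells in the top 25% by MAPK targets (45 UMIs or more) were compared with cells in the bottom 25% (24 or fewer), 2817 cells each. Notch targets rose with MAPK targets. Of 12 compared members 11 had an interval above 1, and their median log2 fold of 1.11 lay above all random lists (central 95% -0.20 to 0.36). The progenitor markers (median 1.06, 8 of 8 members higher), gut transcription factors (0.84, 7 of 8), Hippo targets (0.84, 6 of 8), ecdysone genes (0.74, 8 of 8), JNK genes (0.60, 7 of 9), imaginal disc markers (0.97, 3 of 4) and G2/M genes (0.19, 10 of 20) also lay above the central 95% of random lists, as did the JAK-STAT genes (0.39, 6 of 8). The UMI minimum left out some lineage markers. Of the 12 progenitor markers, esg (19 UMIs in the top against 22 in the bottom class), Sox21a (3 against 2), Sox100B (fold 0.682) and spdo (1.94) were not compared. Of the 15 gut transcription factors, esg, nub, pros, GATAe, fkh, cad and Ptx1 were not compared. The Notch target list shares E(spl)mbeta-HLH and klu with the progenitor list and peb with the gut transcription factors. In 12 alternatives the gut transcription factors fell inside the central 95% in 1, the G2/M genes in 2 and the JAK-STAT genes in 6. The S phase median of -0.08 lay at percentile 32.2. The highest folds were those of twit at 5.37 (4.70 to 6.15), CG13375 at 5.19, Egfr at 4.74 (3.95 to 5.73), Ca-alpha1T at 4.66, the zinc finger gene peb at 4.58 and ab at 4.38. Ypel, Muc14A, salm, brk, mirr, inaE, mol, ed and dve followed, between 4.09 and 3.62. With classes formed within clusters 14 of the 15 moved by over 1.5 times, twit to 1.05 (0.946 to 1.16), CG13375 to 1.64, Egfr to 2.16 (1.85 to 2.54) and peb to 2.34, and mol, at 3.91, was the highest. Those classes overlapped in score, with top cells from 27 UMIs and bottom cells up to 42. The mix of clusters and this overlap thus cannot be told apart as causes of the shifts.

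Immune effectors were again lower, all 9 compared members with an interval below 1 and a median log2 fold of -2.49, as were all 4 iron and metal genes (-0.83). A Drs UMI was found in 942 top and 1123 bottom cells. With classes formed within clusters the immune effector median was -1.36, with an interval below 1 in 5 of 7 members, and cluster 1 had 35.0% of its cells in the bottom and 13.4% in the top class. The neuron markers (-0.55 over 5 members, 3 of them lower) and enteroendocrine markers (-0.44 over 3 members, of which ITP was 1.92-fold higher) lay below the central 95% of random lists, but fell inside it in 3 of 10 and 5 of 11 alternatives, among them classes formed within clusters (-0.14, percentile 13.9, and -0.11, percentile 19.45), and the enteroendocrine median was 0.24 when the third of cells with the highest and that with the lowest scores were compared. The lowest folds were those of ssp7 at 0.0288 (0.0160 to 0.0479), CG30148 at 0.0514, CG13177 at 0.0570, Mtk at 0.0757 and CG15550 at 0.0943, and DptB, Ance, IM33, Mtkl, AttB, Drs, CG10814, Dro, Tsf1 and fne lay between 0.0980 and 0.184. Clusters entered the classes unequally, with 68.4% of cluster 12 in the top and 68.9% of cluster 6 in the bottom class. With classes formed within clusters, 10 of the 11 lowest genes that could be compared moved by over 1.5 times, among them CG13177 to 0.284, Mtk to 0.334 and Drs to 0.268, the log2 folds of CG15550 and Ance turned to 1.80 and 0.011, that of Ca-alpha1T turned to -0.27, and the Notch target median was 0.63, against 1.71 between the top and bottom 10% of cells. Within clusters, the junction (0.47), matrix (0.47), Ras pathway (0.45), BMP, Wnt and Hh (0.38) and sex and dosage compensation (0.37) medians also lay above the central 95% of random lists and those of heat shock (-0.33) and glycolysis (-0.34) below it. Only the Notch targets were also compared with lists matched on gene span. Span matters here, as the longest 5% of genes had a median log2 fold of 0.49 and the shortest 5% one of -0.11. Without the highest cell of each class, CG30148 moved from 0.0514 to 0.0281 and Dro from 0.178 to 0.0875. Of 5196 genes, 177 were at least 2 times higher and 151 at least 2 times lower. The median mitochondrial share was 2.86% in the top and 2.30% in the bottom class, and 574 and 830 cells lay within 1 UMI of the class limits.

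**Figure D3:**
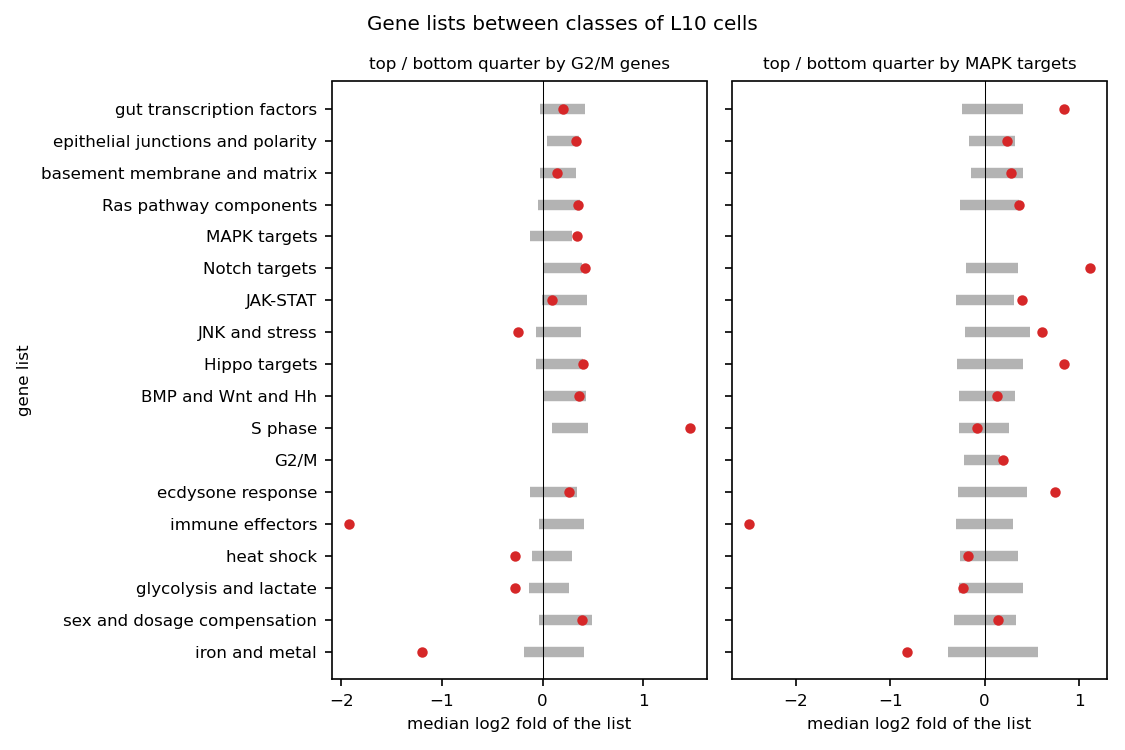
Median log2 fold of each gene list (points, horizontal axis) in the top against the bottom class by G2/M genes (left) and by MAPK targets (right); grey bars are the central 95% of 10000 random lists matched on expression. The S phase list stood at 1.46 on the left and -0.08 on the right, the Notch targets at 0.42 and 1.11, and the immune effectors at -1.93 and -2.49.

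Of the planned pairs of markers, only Egfr with pnt had both genes in at least 1% of thinned cells. Egfr was found in 8.43% and pnt in 93.4% of the 11271 cells, and both in 8.14% (7.65 to 8.67) against 7.87% if independent, a ratio of 1.03 (0.971 to 1.10). With pnt in nearly all cells this ratio could not exceed 1.07, so it does not show whether the genes vary together. The pairs with esg fell below the minimum, since esg had a UMI in 0.497% of thinned cells, and pros with nub did so through nub at 0.195%.

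Of the 30 genes of highest Fano factor, 6 were immune effectors of the fixed list, which had 12 members among the 6228 genes compared. The factor was not corrected for level, and the mean thinned count was 985 for DIP-alpha and 0.497 for Mtk. The highest Fano factor was that of Drs at 582, with a UMI in 35.4% of thinned cells, followed by blot (292) and DIP-alpha (218), against a median of 1.13. The antimicrobial peptide genes Mtk (110), DptB (68.0), AttD (35.2), AttB (26.1) and Dro (22.3), the related Mtkl (26.2) and the stress-induced TotM (46.5) were among the 30 highest. So were the small heat shock genes Hsp23 (81.0) and Hsp26 (49.3), with CG8369 (96.4), CG15550 (91.6), CG13177 (84.4), Obp44a (72.2), Nplp2 (63.8), Cys (61.5), Tsf1 (39.6), Ance (35.2), Act79B (32.1), Arc1 (31.0), Ldh (18.7) and regucalcin (18.6). The rest, ssp7, CG14275, CG42394, CG34296, CG31676 and CG10814, lay between 29.2 and 18.4. Some of these values rested on few cells, since without its highest cell CG8369 fell to 31.1, AttB to 14.2 and CG14275 to 6.27, while Drs stood at 516. With every gene ranked without its highest cell, 26 of the 30 stayed, 5 of them immune effectors, as AttB left.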

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

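Alternatives without the tenth of cells with the highest Scrublet scores, without DIP-alpha counts and with classes formed within clusters were chosen after the data were seen. The median depth was 10616 UMIs with no cell filter, 12205 under the stricter filter and 11045 without the cells of highest Scrublet scores. The count of cell type markers was 26 at a minimum of 50 CPM and stayed between 46 and 59 otherwise. The S phase median was 0.75 and 0.74 in the random subsets A and B, 0.81 at 3500 UMIs per cell, 0.72 with at least 2000 summed UMIs and 1.07 between the top and bottom 10%, settings in which 3 to 9 S phase genes could be compared in place of 14, and 1.28 between the third of cells with the highest and that with the lowest scores, for which the cause was not tested. The Notch target median was 1.19 in subset B, 1.17 without the cells of highest Scrublet scores, 1.71 between the top and bottom 10%, 0.93 for the third of cells at either end, 1.36 with unthinned counts, 1.18 at 3500 UMIs, 1.21 without DIP-alpha counts and 0.63 with classes formed within clusters, always above 0, and the cause of the shifts was not tested. The Egfr and pnt ratio was 1.14 (1.05 to 1.23) at 3500 UMIs, where it could not exceed 1.23. Of the 30 genes of highest Fano factor, 15 were shared at a mean of at least 0.5, where fewer genes qualify. The remaining 46 of these 66 values moved by less than their interval, or by at most 1.5 times for counts, including 10 to 17 clusters of at least 50 cells. Of the other values, 189 of the levels and shares moved and 434 did not, and single genes and lists moved in 227 cases in the cell cycle split and 277 in the MAPK target split, against 288 and 264 that did not. Signs turned in 7 further values, counting named genes and list medians outside the central 95% of random lists, for which the cause was not tested. Medians inside it changed sign in 4 cases in the cell cycle split and 10 in the MAPK target split, among them, with classes formed within clusters, hemocyte (-0.047) in the former and muscle (0.19) and hemocyte (0.24) in the latter. List medians outside it fell inside it in 24 of 127 cases in the cell cycle split and 17 of 153 in the MAPK target split, and medians inside it fell outside it in 20 of 138 and 19 of 114 cases. The immune effector median stayed below all random lists, between -2.87 and -1.70 in the cell cycle split and between -3.16 and -1.36 in the MAPK target split. With classes formed within clusters, the log2 folds were 0.12 for CG15550 and 0.17 for Antp in the cell cycle split, and -0.27 for Ca-alpha1T, 1.80 for CG15550 and 0.011 for Ance in the MAPK target split. The enteroendocrine median was 0.24 in the MAPK target split for the third of cells at either end, and the muscle median 0.11 in the cell cycle split without DIP-alpha counts. Removal of doublets called by Scrublet was not run because it called none, and the roX alternatives were not run. No paired analysis was possible because each line had 1 library. Depth limits what a level near 0 shows: 1 UMI over all kept cells is far below 1 CPM, yet free RNA can supply such UMIs.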

Other observations

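The tests of DIP-alpha in the neuron-like cluster, of noncoding RNAs within abundant genes, of GFP between clusters and in cluster 1, of w in every cluster and of Notch targets within clusters, and the comparisons of glycolysis genes, MAPK targets, other gene lists, w, y and Hsp70Bb by GFP and of Antp, chinmo, fru, Mef2 and sex-determination genes between clusters, were chosen after the results were seen, while the tests of Ras85D with GFP and of gene span were set before their own results, in classes added once the data had been seen. The Hox gene Antp stood at 850 CPM in cluster 6 and 682 CPM in cluster 14, against 1.22 CPM in cluster 7. The temporal identity factor chinmo stood at 1557 CPM in cluster 8, 895 CPM in cluster 6 and 220 CPM in the neuron-like cluster, against 3.87 CPM in cluster 3. fru was highest in cluster 8 (557 CPM) and cluster 6 (342 CPM), and Mef2 in cluster 8 (321 CPM).

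Sex-determination genes also differed between clusters. msl-2, the dosage compensation gene whose translation Sxl represses, ranged from 5.26 CPM in cluster 6 to 21.2 CPM in cluster 10, and Sxl from 116 CPM in cluster 7 to 338 CPM in cluster 13. The 3 clusters of highest msl-2, clusters 10, 7 and 1, had 21.2, 20.3 and 19.3 CPM of it with Sxl at 144, 116 and 134 CPM. The 3 of lowest msl-2, clusters 6, 3 and 12, had 5.26, 5.57 and 6.25 CPM with Sxl at 206, 295 and 318 CPM. Within clusters, several gene lists differed with GFP. Cells with more GFP had more of all 13 glycolysis genes (median log2 fold 0.29, above all random lists). Immune effectors (-0.83, all 8 compared members) and matrix genes (-0.23, 11 of 14) were lower, both medians below all random lists. The Ras pathway (0.24, percentile 99.92), muscle (0.29, 99.5) and heat shock (0.15, 98.24) medians were high among random lists. Those of G2/M (-0.11, percentile 0.07), S phase (-0.12, 0.58) and enteroendocrine genes (-0.18, 2.09) were low. Of 11 MAPK targets 9 had an interval above 1, with a median of 0.14 at percentile 93.9.

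DIP-alpha took more UMIs than any other gene. Expression by neuron-like cells cannot account for it, since the neuron-like cluster had 1.008 times the DIP-alpha CPM of the other cells. A candidate explanation is that reads of a noncoding RNA in an intron of the same strand were assigned to the gene around it. Of the 20 most abundant nuclear genes 2, DIP-alpha and blot, hold such an RNA, against a median of 0 in random sets matched on gene span, whose central 95% reached 2, so the count decides nothing and these reads cannot be told apart from those of DIP-alpha itself in a matrix of genes. blot stood at 43054 CPM in the neuron-like cluster and at 1258 CPM in cluster 1, and no biological explanation from the design was tested.

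GFP differed between cells although its driver gene CG10116 was near 0. Free RNA spread evenly over droplets cannot give the 6.461-fold range of GFP CPM between clusters, and counting noise cannot give the 21.55% of thinned cluster 1 cells with 0 GFP UMIs, where the Poisson share is 0.0243%. Within clusters, Ras85D was 1.271 times higher (1.22 to 1.32) in the top than in the bottom 25% of cells by GFP, with an interval above 1 in 10 of 15 clusters, which may reflect driver activity shared by the UAS transgenes, though its fold lay only at percentile 95.5 of the 5235 genes compared and the unthinned depth was 14423 UMIs in the top against 12807 in the bottom class. The eye and body colour genes w and y, carried as markers by many fly transgenes, rose 3.61-fold and 3.71-fold and Hsp70Bb, 1 of several near-identical copies, 5.30-fold, and w had an interval above 1 in 14 of 15 clusters, but not in cluster 11, where y was lower (0.727). Driver activity shared by the transgenes, loss or silencing of inserted DNA in part of the cells, and cells of another genotype stay open as hypotheses. They could not be separated here.

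Notch targets rose with MAPK targets. A different mix of clusters in the 2 classes was not enough to give this, since with classes formed within clusters the median stayed at the 100th percentile of random lists. A higher share of unspliced RNA in the top class may contribute to other genes, as the longest 5% of genes had a median log2 fold of 0.49 and the shortest 5% one of -0.11. The Notch targets are short, with a median span of 980 bases against 3189, and their median of 0.6304 lay above the central 95% of random lists matched on span (-0.22 to 0.05). The rise was not particular to Notch targets. Within clusters the gut transcription factor (0.80), progenitor (0.71), ecdysone (0.68) and Hippo (0.64) medians were as high or higher. These lists were not matched on span, and the first 2 share members with the Notch list. A link between both pathways in single L10 cells stays a hypothesis, found and tested on the same library, and no biological explanation from the design was tested.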
